A study of Mus musculus with 23 samples.

How the data were processed

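RNA was taken with TRIzol from F9 cells, and libraries were made with TruSeq V2 kits and read as single ends of 72 bp on a Genome Analyzer IIx or 50 bp on a HiSeq, per the labels, which do not say which library had which. Per the submitters' processing notes, TopHat2 2.0.7, HTSeq and DESeq were used for mRNA and Bowtie 0.12.9 and MACS 1.4.2 for ChIP, on build mm9, with no options given. The mRNA values are raw read counts per Ensembl gene, 1 table per library, deposited by the authors without normalization. The RAR and RXR regions were deposited by the authors as 1 list of start and end positions, without a score, a sample or a time, and whether peaks were called per sample or on pooled samples is not stated. ChIP and total chromatin reads were not used here.

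Each count table held 36814 genes, 31841 of them with a symbol, and 5 entries for reads given to no gene, which held 72.52 to 76.78% of all counts in the table and were left out of the totals. TMM factors lay between 0.9291 and 1.095. Counts were fitted with edgeR 4.0.16 in R 4.3.3, in 1 quasi-likelihood model of all 14 mRNA libraries with 1 term per group, TMM normalization, robust estimation and edgeR's default filter for low counts by group. It kept 16155 genes, 15508 with a symbol. All gene p-values are two-sided, from edgeR's quasi-likelihood F-test unless DESeq2 is named, and adjusted by the Benjamini-Hochberg method over the genes tested. A gene was called at an adjusted p under 0.05. CPM values are scaled by TMM. Groups of 1 or 2 libraries were assumed to vary like the others.

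Gene lists were tested with camera from limma 3.58.1 on log2 CPM with a prior count of 3, at a preset correlation of 0.01 between genes and again with an estimated correlation, and adjusted over the 38 lists with at least 5 tested genes. The gene lists, comparisons, tests and the rule for naming genes were chosen before the data were examined. By that rule the text names, for each RA time against 0 h, the 6 genes with the largest increase and the 6 with the largest decrease among called genes with a mean of at least 5 CPM whose RA libraries all lay beyond all 0 h libraries. It names 5 each way for RA against DMSO and found none for DMSO against 0 h. It adds fixed genes whatever their result, and up to 4 list members with the largest changes. Some of those were passed over for members whose calls did not rest on 1 library, and members that ran against their list were added, after their values were seen. Values of 3 genes that the rule, the fixed genes or the lists name are not reported here. Where a gene had 0 counts at 0 h, the fold is a lower bound against a floor of 3 counts over the group, and with 1 to 3 counts it is a ratio of counts with a 95% interval.

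Libraries were sorted into 2 sets after the data were examined, by the share of reads given to no feature among those given to a gene or to no feature. Deviations of the number 1 libraries from their number 2 partners correlated between groups across genes (r from 0.66 to 0.792, median 0.687, over 10 pairs of groups). In each of these groups number 1 lay in set 1 and number 2 in set 2. The correlation therefore cannot tell paired cultures from the set difference. The replicate block below used only replicates 1 and 2 of 0 h and the RA times, so it marks the same split as the set term. Chi-squared per degree of freedom was 10.8 to 17.96 between 0 h libraries within set 2, and 34.51 to 66.92 between replicates of different sets, so the spread exceeded counting error. The alternatives planned were RLE normalization, DESeq2 1.42.0, no filter for low counts, a filter of at least 1 CPM in 4 libraries, the replicate number as a block, 1 surrogate variable from sva 3.50.0, an absolute log2 fold change of at least 1, only the groups compared, and each library left out. A term for the library set, set 2 alone, that term without replicate 1 of 24 h, and DESeq2 with that term were added after seeing the data.

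The fit was tested on simulated data with this layout, in which 100 genes were changed 2-fold and 100 genes 4-fold. For RA at 48 h against 0 h it recovered 19% and 68% of them and called 0 unchanged genes, and with the set term it recovered 54% and 92% and called 13. Here and for DMSO the counts were drawn with a set effect and the spread of the set-term fit, which favours that term. Far fewer genes were changed than were called at 48 h in the data, so recovery there can differ. Regions were counted with Python 3.11.15, NumPy 2.4.6 and SciPy 1.17.1, and the plots were drawn with matplotlib 3.10.9. The mm9 genome and gene positions were not available, so planned tests of regions near changed genes and of direct repeats in regions were not run. A later mouse annotation served only for gene names, gene types and the number of genes per chromosome.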

Results

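Gene expression and retinoid receptor binding were measured in F9 cells, a mouse embryonal carcinoma line that turns toward extraembryonic endoderm when it is given retinoic acid. The cells received all-trans retinoic acid (RA) at 1e-07 M, or dimethyl sulfoxide (DMSO), its solvent, at 0.001%. The series holds 23 samples, of which 14 are mRNA libraries, 8 are chromatin immunoprecipitation (ChIP) libraries and 1 is total chromatin. ChIP of the RA receptors (RAR) and of their partners, the retinoid X receptors (RXR), was done once each at 0, 2, 24 and 48 h. The mRNA libraries comprise 4 at 0 h, 2 each after 6, 12, 24 and 48 h of RA, and 1 each after 24 and 48 h of DMSO. Each mRNA library held 7.079 to 10.95 M (mega) counts on genes, and 16965 to 19671 genes had at least 1 count. Changes are given as log2 fold changes with an approximate standard error (SE). It was taken as the absolute log2 change divided by the square root of the F statistic of its test. Levels are given as mean CPM (counts scaled to a common library size) with the standard deviation (SD). A p-value here measures only the spread between these libraries, which may be technical, since nothing says that the libraries came from separate cultures.

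The 14 mRNA libraries fell into 2 sets that crossed the time points. Of the reads given either to a gene or to no feature, 57.3 to 59.43% were given to no feature in 7 libraries and 52.51 to 53.77% in the other 7. Such reads can still lie within a gene, and the strand setting of the counting is not given. Set 1 held the number 1 library of 0 h and of every RA time and both DMSO libraries, whose labels give no number, and set 2 held the rest. Set 2 was also deeper, at 9.883 to 10.95 M gene counts against 7.079 to 9.165 M. Across all groups 6794 genes (42.1% of those tested) differed between the sets, 3549 higher in set 2 and 3245 lower. The main axis of variation followed time in RA and carried 35.8% of the variance, and the next followed the set and carried 30.2%. On the main axis the DMSO libraries of 24 and 48 h lay at -49.28 and -42.8. The only 0 h library of their own set lay at -51.11, below both. The 0 h libraries of set 2 lay at -43.59 to -30.4. Within a set this comparison rests on 1 library at 0 h. Because both DMSO libraries lie in set 1, the totals of genes called are also given with a term for the set, and so are some values of single genes and lists that it changed.

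**Figure D1:**
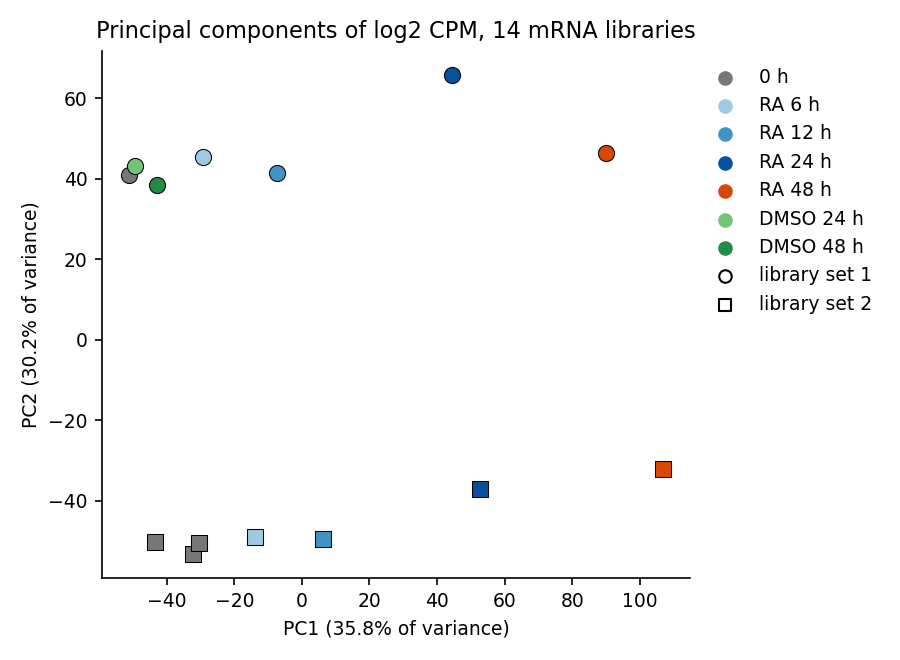
Principal components of log2 CPM in the 14 mRNA libraries, with 1 point per library, colour for the group and symbol shape for the library set. The first component (35.8% of variance) orders the libraries from 0 to 48 h of RA and the next (30.2%) separates the 2 sets.

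The first question was which transcripts respond soonest. After 6 h of RA, genes of the retinoid pathway rose together with genes of the Hox A and Hox B clusters, which encode transcription factors of body-axis patterning. Rarb (ENSMUSG00000017491), a receptor for RA, rose from 0.77 ± 0.308 CPM (SD, n = 4) to 15.1 ± 0.481 CPM (n = 2), a log2 change of 4.26 ± 0.28 (edgeR quasi-likelihood, adjusted p = 6.88e-05). Cyp26a1, an enzyme that degrades RA, rose by 5.08 ± 0.50 and Stra6, a receptor for retinol uptake, by 6.22 ± 0.44. Cyp26b1, another RA-degrading enzyme, had 0 counts in the 4 libraries at 0 h and stood at least 112-fold higher at 9.30 ± 2.66 CPM. Among the 22 tested genes of the retinoid pathway list 9 rose, 0 fell and 10 changed when adjusted over the list alone (camera adjusted p = 2.82e-11). Receptors that did not pass were Rarg at 0.17 ± 0.24, Rxra at -0.29 ± 0.46 and Rara at 0.80 ± 0.38, the last called with the set term (0.61 ± 0.16, adjusted p = 0.032).

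Of 16 genes listed beforehand as early RA targets, 13 rose at 6 h and 15 changed when adjusted over the list alone. Stra8, known from the entry of germ cells into meiosis, rose by 6.47 ± 0.59, and Cdx1, a posterior patterning factor, by 4.22 ± 0.48. In the Hox A cluster 6 of 10 tested genes rose (7 adjusted over the list alone) and in the Hox B cluster 5 of 10 did (7 adjusted over the list alone), with 0 falling in either. Hoxa5 rose by 5.97 ± 0.54. Hoxa4 and Hoxb5 had 3 and 2 counts at 0 h in all, and their count ratios were 77.8 (95% interval 26 to 383) and 224 (61.4 to 1860). Such intervals, and the floor of 3 counts over the group behind each value given as at least a fold, cover counting error only. Hoxb1 rose by 3.58 ± 0.60 (adjusted p = 0.0126), a call lost without replicate 2 or 3 of 0 h or replicate 2 of 6 h, at adjusted p of up to 0.156. Hox genes overlap antisense transcripts, and the strand setting of the counting is not given, so single members of the clusters are uncertain.

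In total 268 genes differed between 6 and 0 h, 237 higher and 31 lower, and each had the same sign within both library sets. Those genes were called from the same libraries, so the selection largely sets this agreement and it is no replication. With the set term 906 were called, 662 higher and 244 lower. The 6 decreases named by rule were those of Zfp608 (-3.56 ± 0.71), Slc27a2 (-2.53 ± 0.44), Pla2g7 (-2.50 ± 0.47), Pim2 (-2.42 ± 0.47), Neurog3 (-2.32 ± 0.44) and Prickle1 (-2.17 ± 0.45). All 6 were lost without replicate 2 of 6 h, 5 of them (not Pla2g7) without replicate 1, and 5 (not Slc27a2) without replicate 2 or 3 of 0 h, at adjusted p of up to 0.406, while Neurog3, Pim2, Pla2g7 and Prickle1 were also lost without replicate 4. The total was 107 without replicate 2 of 6 h, 111 without replicate 1, and 152 and 163 without replicates 2 and 3 of 0 h. Of 38 gene lists tested 7 differed, and 4 did with an estimated correlation, or 3 with the set term as well, which lost Hox B (adjusted p = 0.11). The 3 lists that did not were primitive endoderm (2 of 18 higher, 4 adjusted over the list alone, adjusted p = 0.0345, against adjusted p = 0.719 with an estimated correlation and 0.24 with the set term), MYC and ribosome biogenesis (0 of 20 called, also adjusted over the list alone, and 3 lower with the set term, adjusted p = 0.0345, against adjusted p = 0.404 with an estimated correlation), and ribosomal proteins (0 of 79 called, also adjusted over the list alone, adjusted p = 0.039, against adjusted p = 0.75 with an estimated correlation and 0.269 with the replicate block).

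After 12 h the same groups were again higher than at 0 h, and so were regulators of endoderm that were already called at 6 h. Foxa1, a transcription factor of endoderm, rose from 0.627 ± 0.239 to 21.5 ± 1.74 CPM, a log2 change of 5.08 ± 0.26 (adjusted p = 1.17e-05), and Gata6, which specifies primitive endoderm, rose by 4.43 ± 0.64. At 6 h Foxa1 had risen by 3.97 ± 0.27 and Gata6 by 3.06 ± 0.65, the latter lost without either 6 h replicate or replicate 2, 3 or 4 of 0 h (adjusted p of up to 0.455). Stra8 rose by 7.73 ± 0.60 and Hoxa5 by 7.91 ± 0.53, while Cyp26b1 was at least 275-fold higher and the count ratio of Hoxb2 was 310 (105 to 1510). Dnmt3b and Dnmt3l, which take part in de novo DNA methylation, fell by 1.47 ± 0.27 and 1.99 ± 0.36 on the log2 scale. Both were lost without replicate 1 of 12 h (adjusted p of up to 0.195 and 0.18), and Dnmt3b also without replicate 2. Pla2g7 (-3.58 ± 0.51), Prickle1 (-3.38 ± 0.50), Pim2 (-3.33 ± 0.50), Slc27a2 (-3.15 ± 0.46), Clnk (-3.00 ± 0.65) and Tgm3 (-2.90 ± 0.56) fell most among the genes named by rule. Pla2g7, Clnk and Tgm3 were lost without replicate 2 of 12 h, and all but Pla2g7 without replicate 1. Clnk and Tgm3 were also lost without replicate 2 of 0 h, and Clnk without replicate 3 or 4, with adjusted p of up to 0.25 over the 6 genes.

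Altogether 444 genes differed at 12 h, 348 higher and 96 lower, against 2050 with the set term, 1192 higher and 858 lower. Without replicate 1 of 12 h the total was 167 and without replicate 2 it was 212. The early RA list had 15 of 16 members higher (15 adjusted over the list alone), Hox A 6 of 10 (8 adjusted over the list alone), Hox B 7 of 10 (9 adjusted over the list alone) and the retinoid pathway 10 of 22 (10 adjusted over the list alone). These 4 lists and MYC and ribosome biogenesis also passed with an estimated correlation. With the set term as well only the early RA list did, against adjusted p = 0.0865 for Hox A, 0.115 for Hox B, 0.116 for the retinoid pathway and 0.278 for MYC and ribosome biogenesis. In that last list 0 of 20 genes were called and 3 fell when adjusted over the list alone, with a median change of -0.37 (adjusted p = 2.25e-05) and 9 called lower with the set term. Primitive endoderm had 4 of 18 members higher, among them Gata6, Sox7 and Foxa1, and 4 adjusted over the list alone (adjusted p = 0.00875, but adjusted p = 0.706 with an estimated correlation and 0.111 with the set term). Sox7 (1.28 ± 0.29) was lost without either 12 h replicate or replicate 2, 3 or 4 of 0 h (adjusted p of up to 0.262). Ribosomal protein genes had a median change of -0.34 with 0 of 79 called, also when adjusted over the list alone (adjusted p = 8.07e-05, but adjusted p = 0.533 with an estimated correlation), and 8 called lower with the set term.

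By 24 h more genes of the primitive and parietal endoderm lists were higher, with 0 of 12 visceral endoderm genes called (adjusted p = 0.656), and genes of ribosome production were called lower. Gata6 rose from 1.92 ± 1.62 to 108 ± 32.3 CPM (5.86 ± 0.66, adjusted p = 0.000406) and Foxa1 by 6.23 ± 0.27. Among 18 genes of primitive endoderm 11 rose, 0 fell and 13 changed when adjusted over the list alone (adjusted p = 2.33e-07, but adjusted p = 0.104 with an estimated correlation). Gata4 (2.82 ± 0.45), Foxa2 (4.28 ± 0.78) and Sox17 (2.88 ± 0.78) were among them, and all 3 were lost without replicate 1 of 24 h, at adjusted p = 0.0501, 0.0762 and 0.539. Sox17 was also lost without replicate 2, 3 or 4 of 0 h. Of 26 genes of the parietal endoderm and basement membrane list 10 rose, 1 fell and 14 changed when adjusted over the list alone (adjusted p = 5.92e-05, but adjusted p = 0.16 with an estimated correlation). Collagen IV gene Col4a1 rose by 2.99 ± 0.40 and Plat, a plasminogen activator, by 5.52 ± 0.43. Laminin gene Lama1 rose by 2.46 ± 0.53, a call lost without replicate 1 of 24 h (adjusted p = 0.166). Fst, an inhibitor of activin, fell by 5.09 ± 1.13 on the log2 scale and was likewise lost (adjusted p = 0.0951).

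In the pluripotency list 11 of 30 genes fell at 24 h, 1 rose and 17 changed when adjusted over the list alone (adjusted p = 4.2e-06, but adjusted p = 0.16 with an estimated correlation). Tdh, a threonine-degrading enzyme of pluripotent cells, fell by 3.24 ± 0.24 and Tdgf1, a Nodal co-receptor, by 2.34 ± 0.37 on the log2 scale. Fgf4 (-1.77 ± 0.37) and Sox2 (-1.04 ± 0.26) were lost without replicate 1 of 24 h (adjusted p of up to 0.0933 and 0.147), and Sox2 also without replicate 2 of 24 h or of 0 h. Pou5f1 stood at -0.74 ± 0.34 (adjusted p = 0.19), which the set term turned into a call (adjusted p = 0.0016). Tbx3 was the member that rose, by 2.76 ± 0.56, a call lost without replicate 1 of 24 h (adjusted p = 0.123). Of 20 genes of MYC and ribosome biogenesis 14 fell, 0 rose and 18 changed when adjusted over the list alone (adjusted p = 4.29e-11). Ddx21, a nucleolar helicase, fell by 1.44 ± 0.25, and Myc by 2.41 ± 0.51 on the log2 scale, the latter lost without replicate 2 of 24 h (adjusted p = 0.0707). Of 24 genes of folding and secretion in the endoplasmic reticulum 10 rose, 0 fell and 11 changed when adjusted over the list alone (adjusted p = 2.38e-05), with Creb3l2, a transcription factor of the secretory pathway, up by 2.35 ± 0.31.

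Between 24 and 0 h 1993 genes differed, 1305 higher and 688 lower, against 4689 with the set term, 2506 higher and 2183 lower. Which direction prevailed depended on the fit, since the replicate block gave 2247 higher and 2089 lower and DESeq2 with the set term 2193 higher and 2396 lower. Replicate 1 of 24 h stood apart from the other libraries on a further axis of variation. Without it 712 genes were called, and 3171 with the set term, while 1282 and 1298 were called without replicates 3 and 2 of 0 h. Among the single genes given at 24 h as lost without replicate 1, only Sox17 (log2 change 1.43) was also lost when the set term was added. That fit too has a single library at 24 h. The highest by rule were Cyp26b1 (at least 702-fold), Hoxb2 (count ratio 829, 283 to 4020), Hoxb5 (835, 231 to 6900), Hoxa5 (8.73 ± 0.53), Stra6 (8.66 ± 0.44) and Stra8 (8.44 ± 0.61). The lowest were Vrtn (-5.36 ± 1.21), Lef1 (-5.20 ± 1.49), Clnk (-4.84 ± 0.75), Tgm3 (-4.27 ± 0.62), Zmat4 (-3.97 ± 0.77) and Enox1 (-3.85 ± 0.44). Vrtn, Lef1 and Zmat4 were lost without replicate 1 of 24 h, Vrtn and Lef1 without replicate 2, and Lef1 without replicate 2, 3 or 4 of 0 h, at adjusted p of up to 0.218. Of the lists 13 differed and 6 also did with an estimated correlation, namely early RA genes (15 of 16 higher, 16 adjusted over the list alone), Hox A (8 of 10 higher, 9 adjusted over the list alone), Hox B (9 of 10 higher, 10 adjusted over the list alone), the retinoid pathway (10 of 22 higher, 12 adjusted over the list alone), MYC and ribosome biogenesis, and folding and secretion. Under the set term and an estimated correlation 5 lists passed. The retinoid pathway (adjusted p = 0.058), Hox B (0.0552) and MYC and ribosome biogenesis (0.0552) were lost, and primitive endoderm and basement membrane (0.0452 each) were gained. The retinoid member that fell was the receptor Rxrg (-2.39). Of 22 lysosome and endocytosis genes 3 rose (3 adjusted over the list alone, adjusted p = 0.0196, but adjusted p = 0.102 with an estimated correlation), and of 22 S phase genes 1, Rpa2, fell (1 adjusted over the list alone, adjusted p = 0.00183, but adjusted p = 0.102 with an estimated correlation). Rpa2 (-0.54 ± 0.13) was lost without either 24 h replicate or replicate 3 or 4 of 0 h, at adjusted p of up to 0.102. Of 17 p53 targets 1 rose and 2 fell (5 adjusted over the list alone, adjusted p = 0.0169, but adjusted p = 0.292 with an estimated correlation), and of 79 ribosomal protein genes 6 fell (6 adjusted over the list alone, adjusted p = 8.66e-07, but adjusted p = 0.16 with an estimated correlation). With the set term 11 S phase genes, 8 p53 targets, 29 ribosomal protein genes and 18 pluripotency genes fell, and 5 lysosome and endocytosis genes rose.

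At 48 h every tested gene of the primitive endoderm list was higher than at 0 h, 18 of 18 (18 adjusted over the list alone, adjusted p = 2.98e-11). Foxa2 rose from 0.298 ± 0.202 to 31.5 ± 1.79 CPM (6.76 ± 0.79, adjusted p = 0.000229), Sox17 by 6.74 ± 0.78 and Dab2, an endocytic adaptor, from 5.59 ± 5.42 to 593 ± 26.5 CPM (6.74 ± 0.90), although not called within set 2 alone (adjusted p = 0.0562). Gata6 rose by 6.14 ± 0.66, Gata4 by 4.12 ± 0.46 and Sox7 by 1.95 ± 0.28. In the parietal endoderm and basement membrane list 19 of 26 rose, 0 fell and 20 changed when adjusted over the list alone (adjusted p = 9.58e-09). Collagen IV transcripts Col4a1 and Col4a2 rose by 4.95 ± 0.42 and 5.24 ± 0.61, reaching 1790 ± 179 and 1240 ± 339 CPM. Laminin transcripts Lama1 and Lamb1 rose by 4.48 ± 0.55 and 3.33 ± 0.24, Plat by 7.98 ± 0.44 and Srgn, a proteoglycan core protein, by 5.80 ± 0.64. Of 12 tested visceral endoderm genes 9 rose, 0 fell and 10 changed when adjusted over the list alone (adjusted p = 9.21e-06). Cubn, an endocytic receptor, rose by 4.56 ± 0.87, and Ttr, a thyroxine carrier, had 1 count at 0 h and a count ratio of 629 (112 to 24900). Ttr was not called by DESeq2 (adjusted p = 0.152). Apob (4.56 ± 0.93) and Spink1 (4.52 ± 0.98) were lost without replicate 2 of 48 h, at adjusted p = 0.0821 and 0.0539. Afp, a marker of late visceral endoderm, had too few counts to be tested.

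Transcripts for secretion and endocytosis rose with these. Of 24 genes of folding and secretion 18 rose, 0 fell and 18 changed when adjusted over the list alone (adjusted p = 3.09e-07). Creb3l2 rose by 3.57 ± 0.31, Serpinh1, a collagen chaperone, by 3.28 ± 0.36, Kdelr3, a retrieval receptor, by 3.21 ± 0.36, and P4ha2, a collagen prolyl hydroxylase, by 2.52 ± 0.22. Of 22 lysosome and endocytosis genes 19 rose, 0 fell and 21 changed when adjusted over the list alone (adjusted p = 2.25e-09). Lrpap1, a chaperone of endocytic receptors, rose by 2.75 ± 0.24, and the protease Ctsh, with 3 counts at 0 h, had a count ratio of 18.8 (5.90 to 95.8). Dab2 and Cubn belong to this list too. The largest increases by rule at 48 h included those of Cyp26b1 (at least 258-fold), Hoxb2 (count ratio 579, 198 to 2810), Gpr50 (8.81 ± 0.77), Foxf2 (count ratio 545, 150 to 4510) and Foxq1 (8.19 ± 0.74).

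Pluripotency transcripts fell at 48 h in 21 of 30 cases, 2 rose and 24 changed when adjusted over the list alone (adjusted p = 9.72e-09, but adjusted p = 0.0677 with an estimated correlation). Pou5f1 (ENSMUSG00000024406), a core factor of pluripotency, went from 2120 ± 292 to 647 ± 359 CPM (-1.71 ± 0.36, adjusted p = 0.00569), Nanog from 313 ± 65.5 to 128 ± 8.53 CPM (-1.29 ± 0.27) and Sox2 from 570 ± 178 to 210 ± 61.3 CPM (-1.44 ± 0.27). Pou5f1 and Nanog were lost without replicate 2 of 48 h, at adjusted p = 0.0556 and 0.0585, as were Zfp42 (-1.29 ± 0.31, adjusted p = 0.116) and Esrrb (-0.69 ± 0.16, adjusted p = 0.128). Decreases also included those of Tdgf1 (-3.95 ± 0.41), Fgf4 (-3.11 ± 0.41) and Tdh (-2.98 ± 0.24). Dppa3, at 1.80 ± 1.42 CPM at 0 h and 0 CPM at 48 h, was called (adjusted p = 0.0328) but lost without either 48 h replicate or without replicate 2, 3 or 4 of 0 h, at adjusted p of up to 0.141. The members that rose were Klf4 (2.41 ± 0.43) and Tbx3 (2.82 ± 0.56), both transcription factors that also act outside pluripotent cells. Dnmt3l fell by 2.60 ± 0.37, and Dnmt3b fell by 0.96 ± 0.26 on the log2 scale, a call lost without replicate 1 of 48 h (adjusted p = 0.15).

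Growth-related transcripts fell over the same span. Of 20 genes of MYC and ribosome biogenesis 17 fell, 0 rose and 18 changed when adjusted over the list alone (adjusted p = 3.81e-10). Myc fell by 2.68 ± 0.51, Ddx21 by 1.73 ± 0.25 and Rrp12, a ribosome assembly factor, by 1.73 ± 0.21 on the log2 scale. Of 79 ribosomal protein genes 31 fell, 0 rose and 39 changed when adjusted over the list alone, with a median change of -0.84 (adjusted p = 4.46e-11, but adjusted p = 0.0596 with an estimated correlation), and 67 fell with the set term. Many ribosomal protein genes have near-identical copies in the genome, so the counts of single members are uncertain. Of 22 S phase genes 16 fell, 0 rose and 17 changed when adjusted over the list alone (adjusted p = 5.89e-08). Ccne1, cyclin E1, fell by 1.30 ± 0.22 and Rrm2, a subunit of ribonucleotide reductase, by 1.19 ± 0.20 on the log2 scale. Pcna (-1.43 ± 0.41) was lost without either 48 h replicate (adjusted p of up to 0.146) and Uhrf1 (-1.05 ± 0.24) without replicate 2 (adjusted p = 0.096). Of 22 genes of the G2 and M phases 7 fell, 0 rose and 7 changed when adjusted over the list alone (adjusted p = 0.00622, but adjusted p = 0.524 with an estimated correlation), and 11 fell with the set term. Of 16 growth-arrest genes 8 rose, 0 fell and 8 changed when adjusted over the list alone (adjusted p = 0.0164, but adjusted p = 0.104 with an estimated correlation). Cdkn2a, an inhibitor of cyclin-dependent kinases, rose by 1.96 ± 0.29 and Ccng2 by 1.82 ± 0.28. Ccng2 stood at 18.9 CPM in the library of 48 h DMSO, against 7.89 ± 1.76 CPM at 0 h and 27.9 ± 10.1 CPM with RA, and was not called between RA and DMSO at 48 h (0.56 ± 0.42, adjusted p = 0.44). Cdkn1a, the p53 target p21, rose by 0.60 ± 0.18, a call lost without replicate 1, 3 or 4 of 0 h or replicate 2 of 48 h (adjusted p of up to 0.293). Of 23 nuclear genes of oxidative phosphorylation 4 fell and 0 rose, also adjusted over the list alone (adjusted p = 0.000945, but adjusted p = 0.31 with an estimated correlation), and 13 fell with the set term.

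The Hox clusters and the retinoid pathway stayed high at 48 h. In Hox B 10 of 10 genes rose (10 adjusted over the list alone), in Hox A 9 of 10 (10 adjusted over the list alone), and among early RA genes 15 of 16 (16 adjusted over the list alone). Of 14 tested Hox C and D genes 8 rose, 1 (Hoxd11) fell and 10 changed when adjusted over the list alone (adjusted p = 0.00109, but adjusted p = 0.31 with an estimated correlation). Hoxc5 had 1 count at 0 h and a count ratio of 248 (43.8 to 9860). Hoxc8 and Hoxc9 had 0 counts at 0 h and were at least 104-fold and 86.6-fold higher, but DESeq2 called neither (adjusted p = 0.167 and 0.182). Of the retinoid pathway 13 of 22 rose, 2 fell and 16 changed when adjusted over the list alone (adjusted p = 9.21e-06). Rarb reached 50.9 ± 4.77 CPM (6.01 ± 0.29) and Dhrs3, a retinal reductase, 46.0 ± 8.51 CPM (6.08 ± 0.37). Rarg fell from 593 ± 89.7 to 142 ± 50.7 CPM (-2.06 ± 0.27) and Rxrg by 4.28 on the log2 scale. Rara stood at -0.73 ± 0.40 (adjusted p = 0.20), and was called with the set term (-0.86 ± 0.17, adjusted p = 0.0007) and with the replicate block (-0.76, adjusted p = 0.00403), while Rxra stood at 0.26 ± 0.45 (adjusted p = 0.70). The term and the block mark the same split of libraries, so these calls of Rara are not separate evidence. Cdx1 was down to 7.03 ± 0.502 CPM at 48 h, still called against 0 h (1.65 ± 0.48, adjusted p = 0.0268) but lost without either 48 h replicate or without replicate 3 or 4 of 0 h (adjusted p of up to 0.122).

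In all 4766 genes differed between 48 and 0 h, 2826 higher and 1940 lower, and 4765 had the same sign within both library sets. That agreement is again largely set by selecting the genes from these libraries. The set term gave 7881, 4175 higher and 3706 lower. Without replicate 1 of 48 h 2731 were called and without replicate 2 2762. The lowest by rule were Grhl2 (-6.05 ± 1.4), an epithelial transcription factor, Tgm3 (-5.89 ± 0.71), Vrtn (-5.86 ± 1.26), Clnk (-5.77 ± 0.81), the splicing factor Esrp1 (-5.06 ± 1.47) and Rasgrp2 (-4.60 ± 0.34). Grhl2, Vrtn and Esrp1 were lost without either 48 h replicate, and Esrp1 without replicate 3 of 0 h, at adjusted p of up to 0.159. Of 38 lists 18 differed and 11 also did with an estimated correlation, or 5 with the set term as well. That lost Hox A, S phase and MYC and ribosome biogenesis (adjusted p = 0.0693 each), the retinoid pathway (0.0723), Hox B (0.0954) and visceral endoderm (0.128). Among markers of other cell types, 7 of 10 fibroblast genes rose, 1 fell and 10 changed when adjusted over the list alone (adjusted p = 0.000785, but adjusted p = 0.128 with an estimated correlation). Tagln, an actin-binding protein of smooth muscle and fibroblasts, rose by 4.02 ± 0.35 to 33.7 ± 11.3 CPM, Thy1 fell by 4.02 ± 0.51 on the log2 scale, and Dcn, an abundant fibroblast proteoglycan, reached 1.26 ± 1.64 CPM. Lists of blood and endothelium (2 of 7 higher, 1 lower), germ cells (3 of 12 higher, 1 lower), muscle and neuron (1 of 7 higher, 1 lower), mitochondrially encoded mRNA (0 of 7 called) and replication-dependent histones (0 of 9 called) did not differ. Neither did neural ectoderm (7 of 16 higher, 3 lower, adjusted p = 0.282), gastrulation and mesoderm (6 of 16 higher, 1 lower, adjusted p = 0.145) or trophectoderm (4 of 12 higher, 0 lower, adjusted p = 0.113). Gapdh, with many near-identical copies, stood at -0.76 ± 0.41 (adjusted p = 0.19) and was called with the replicate block (-1.14, adjusted p = 0.0072). Actb stood at -0.18 ± 0.45 (adjusted p = 0.80) and at 0.31 without replicate 2 of 48 h.

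**Figure D2:**
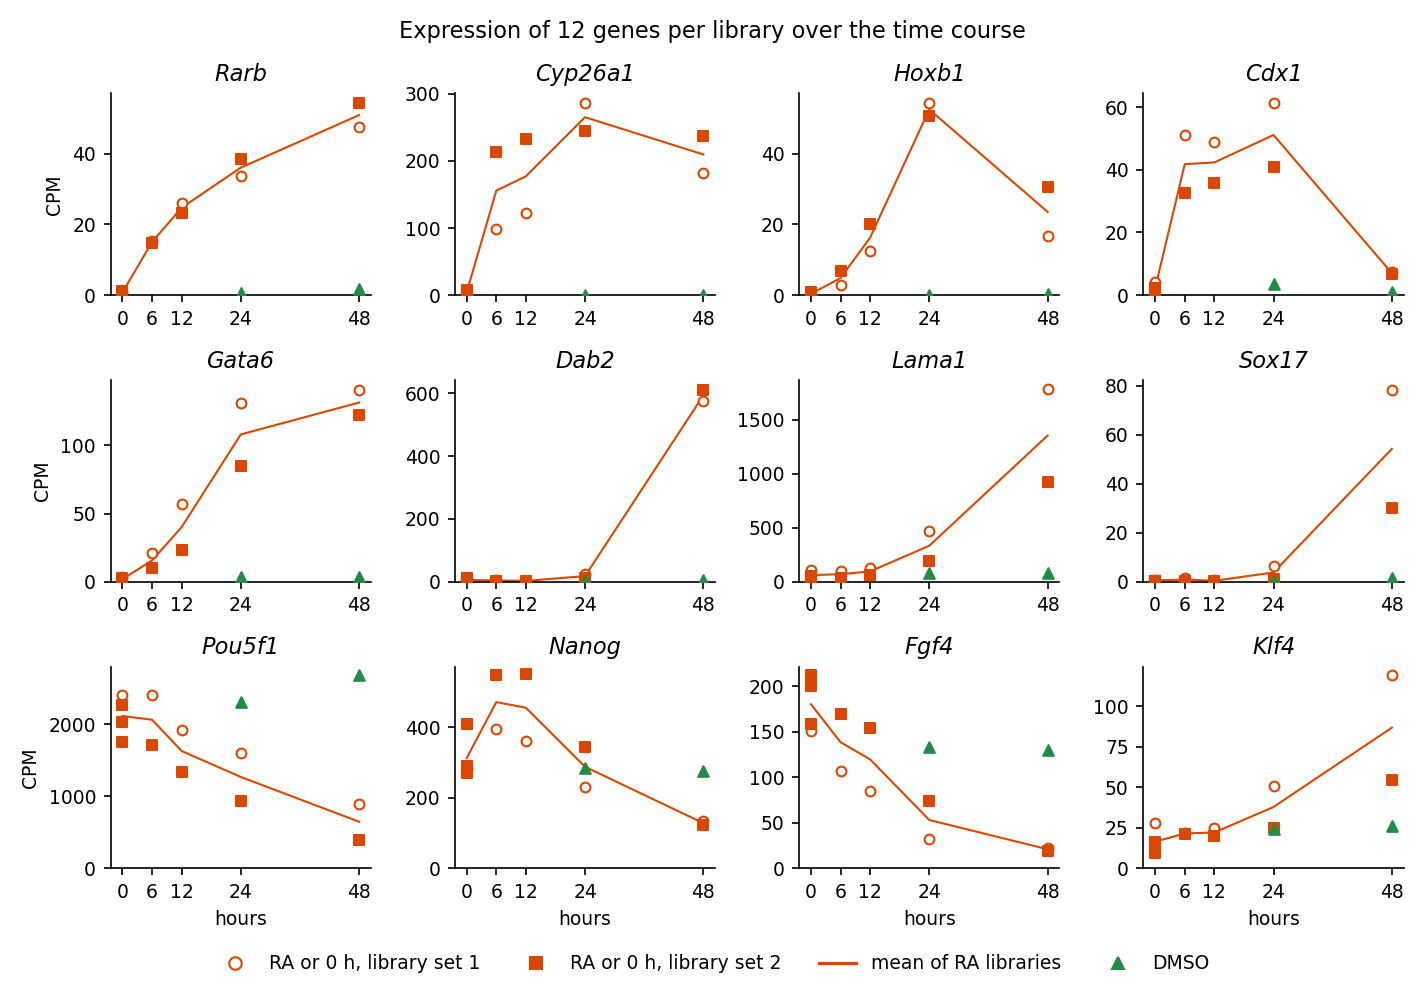
CPM against hours for 12 named genes, with 1 point per library, open circles for set 1, squares for set 2, triangles for DMSO and a line through the means of the RA libraries. Rarb reaches 15.1 CPM by 6 h and 50.9 CPM at 48 h, Dab2 rises between 24 h and 48 h to 593 CPM, and Pou5f1 declines to 647 CPM with RA while its DMSO libraries stand at 2310 and 2690 CPM.

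**Figure D3:**
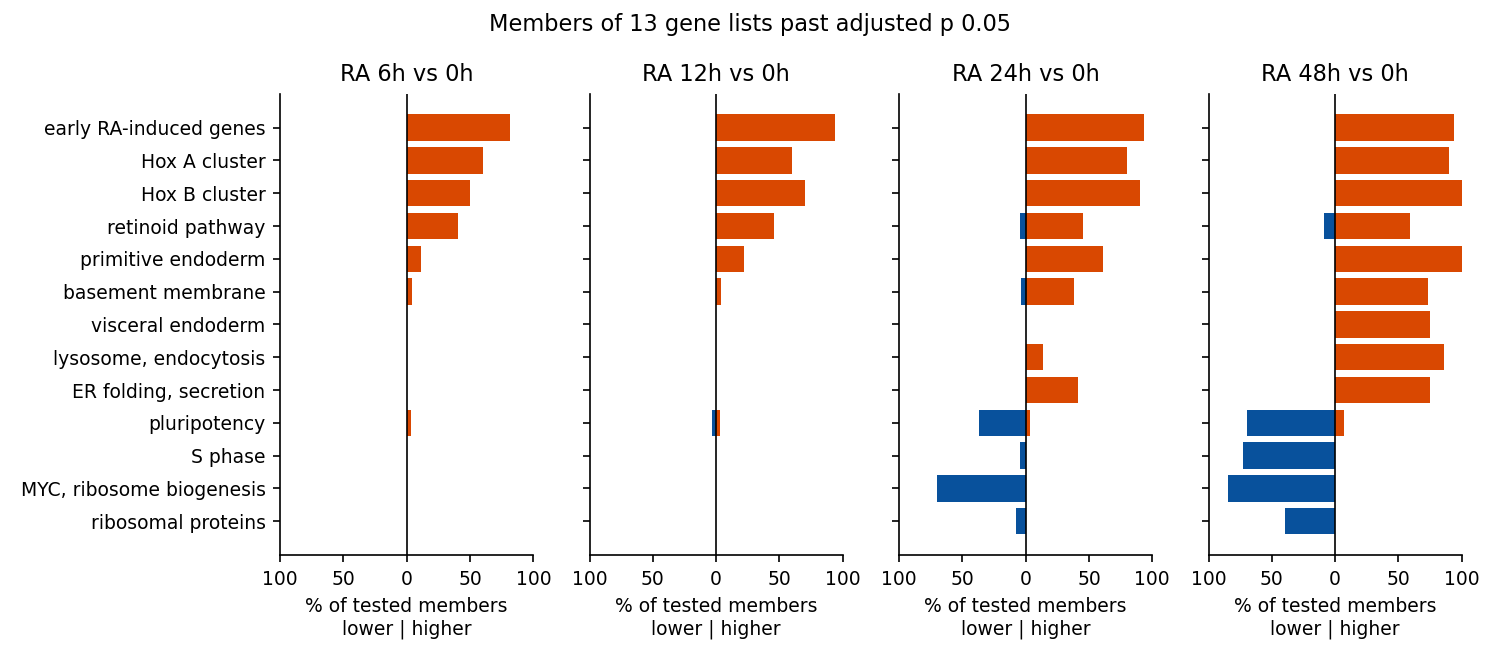
Percent of the tested members of 13 gene lists called higher (right of 0) or lower (left of 0) at each RA time against 0 h. The early RA genes and Hox clusters are already higher at 6 h, while primitive endoderm (18 of 18 higher) and S phase (16 of 22 lower) are most complete at 48 h.

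Over the whole time course 3427 of 16155 tested genes changed, or 7753 with the set term. Without replicate 1 or 2 of 48 h the total was 1929 or 1969. Genes were also counted by the time of their first call against 0 h, whether or not the test over the whole course called them. By this count 237 genes were first higher and 31 first lower at 6 h, 141 and 74 at 12 h, 979 and 614 at 24 h, and 1675 and 1332 at 48 h. With the set term the counts were 662 and 244, 623 and 657, 1565 and 1567, and 1937 and 1722. Between successive times the fit resolved little. Between 12 and 6 h edgeR called 0 genes (287 at an unadjusted p under 0.05), while DESeq2 called 4, which were Hoxb2 (2.29), Crabp2 (2.01) and Zfp703 (1.87), all higher, and Egr1 (-2.55), lower. The set term gave 3, again Hoxb2 (2.28) and Crabp2 (2.00) with Hoxa5 (1.98), and the replicate block 15. Between 24 and 12 h 2 genes were called, both higher, Sfrp5, a secreted Wnt antagonist (4.60, adjusted p = 0.000863), and the metalloproteinase Mmp15 (3.14, adjusted p = 0.0142). All of these were named after their values were seen. Only Sfrp5 was called without either 12 h replicate, and 67 genes, 32 higher and 35 lower, were called without replicate 2 of 24 h. With the set term the count was 1012, 571 higher and 441 lower, with the replicate block 1801, and by DESeq2 with the set term 1574, 710 higher and 864 lower. Between 48 and 24 h 114 genes differed, 79 higher and 35 lower, against 1781 with the set term, 1034 higher and 747 lower, and 2573 with the replicate block. Without replicate 1 or 2 of 24 h that count was 0 or 2, and without replicate 1 or 2 of 48 h it was 29, 14 higher and 15 lower, or 3.

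**Figure D4:**
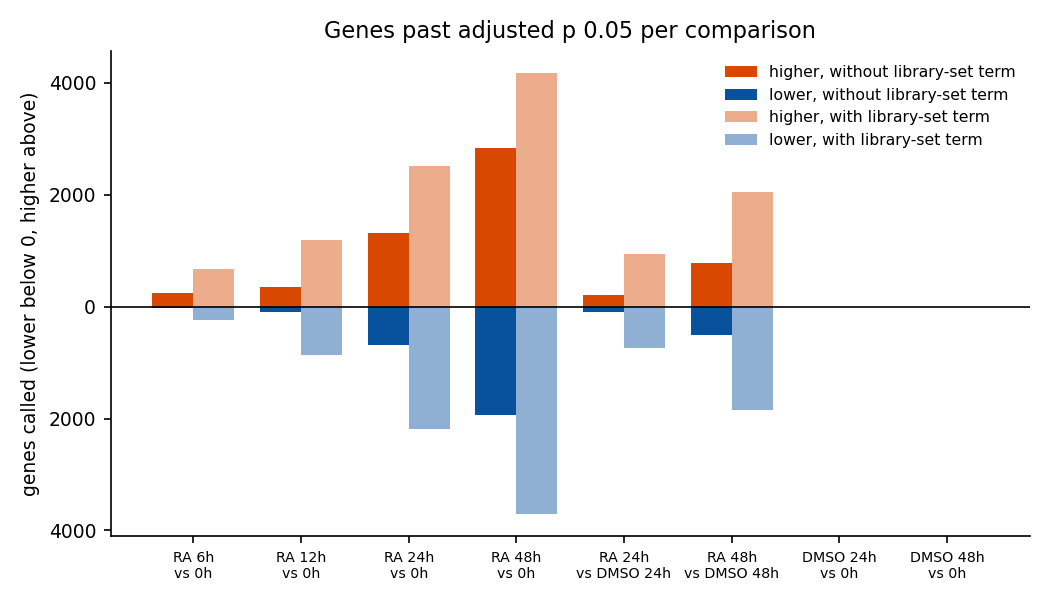
Genes called higher (above 0) and lower (below 0) in 8 comparisons at an adjusted p under 0.05, without and with a term for the library set. Against 0 h the totals without the term grow from 268 at 6 h to 4766 at 48 h, and DMSO against 0 h has 0 at both times.

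To separate the effect of RA from that of time in culture, RA at 24 and 48 h (n = 4) was compared with DMSO at the same times (n = 2). The retinoid, Hox and secretory groups were higher with RA and transcripts of growth lower. Primitive endoderm and basement membrane were also higher and pluripotency lower, but adjusted p = 0.0531, 0.0828 and 0.0828 with an estimated correlation. Cyp26a1 was at 265 ± 29.8 CPM at 24 h and 209 ± 38.8 CPM at 48 h with RA against 0.696 and 0.518 CPM with DMSO, a log2 difference of 8.58 ± 0.83 (adjusted p = 0.000227). Stra8 was at 242 ± 24.7 and 82.0 ± 11.5 CPM with RA against 0 and 0.259 CPM with DMSO, and Foxa2 at 5.67 ± 4.63 and 31.5 ± 1.79 CPM against 0 CPM at both times. Foxa1 (7.13 ± 0.38), Gata6 (4.98 ± 0.80) and Col4a1 (3.31 ± 0.49) were higher with RA. Pou5f1 (-1.46 ± 0.32), Sox2 (-1.88 ± 0.24), Fgf4 (-1.98 ± 0.33), Tdgf1 (-3.01 ± 0.32), Rarg (-1.21 ± 0.24) and Myc (-2.88 ± 0.43) were lower. Pou5f1 and Rarg were not called when only the groups compared were fitted (adjusted p = 0.119 and 0.101). Besides Stra8 and Foxa2 the rule named Cyp26b1, Hoxb2 and Hoxb3 as highest, which had 0, 1 and 0 counts with DMSO, and Vrtn (-4.95 ± 0.95), Clnk (-4.81 ± 0.61), Foxd3 (-4.53 ± 0.70), Slc27a2 (-4.21 ± 0.39) and Enox1 (-4.18 ± 0.36) as lowest. Nanog stood at -0.54 ± 0.25 (adjusted p = 0.16) and was called with the set term (adjusted p = 0.011).

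Of the 38 lists 20 differed between RA and DMSO, and 8 also did with an estimated correlation, or 5 with the set term as well. Those 8 were early RA genes (15 of 16 higher, 15 adjusted over the list alone), Hox A (9 of 10, 10 adjusted over the list alone), Hox B (10 of 10, 10 adjusted over the list alone), the retinoid pathway (10 of 22 higher, 2 lower, 13 adjusted over the list alone), folding and secretion (13 of 24 higher, 17 adjusted over the list alone), lysosome and endocytosis (10 of 22 higher, 15 adjusted over the list alone), S phase (13 of 22 lower, 14 adjusted over the list alone) and MYC and ribosome biogenesis (13 of 20 lower, 17 adjusted over the list alone). With the set term as well Hox A (adjusted p = 0.0509), MYC and ribosome biogenesis (0.0574), the retinoid pathway (0.0619), Hox B (0.0623) and S phase (0.0681) were lost, and primitive endoderm (0.0117) and basement membrane (0.0114) were gained. Pluripotency had 16 of 30 lower and 20 adjusted over the list alone (adjusted p = 1.76e-08, but adjusted p = 0.0828 with an estimated correlation). Primitive endoderm had 11 of 18 higher and 17 adjusted over the list alone (adjusted p = 7.52e-10, but adjusted p = 0.0531 with an estimated correlation), and basement membrane 13 of 26 higher and 16 adjusted over the list alone (adjusted p = 1.38e-06, but adjusted p = 0.0828 with an estimated correlation). Of 79 ribosomal protein genes 10 were lower and 5 when adjusted over the list alone (adjusted p = 6.61e-07, but adjusted p = 0.147 with an estimated correlation), and 28 were lower with the set term. That term also gave 17 of 18 primitive endoderm genes higher and 20 of 20 genes of MYC and ribosome biogenesis lower. Visceral endoderm had 0 of 12 called, also adjusted over the list alone, and 6 higher with the set term (adjusted p = 0.000901, but adjusted p = 0.0943 with an estimated correlation). The other 7 lists that differed were Hox C and D, fibroblast markers, trophectoderm and epithelial junctions, all higher, and glycolysis, DNA methylation enzymes and cholesterol synthesis, all lower, with adjusted p from 0.139 to 0.532 with an estimated correlation. Of these, epithelial junctions, DNA methylation enzymes and cholesterol synthesis did not differ with the set term (adjusted p = 0.109, 0.101 and 0.063), while the G2 and M phases did (adjusted p = 0.00105, against 0.0921 without it).

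The pooled comparison called 2712 genes, 1623 higher and 1089 lower, against 5120 with the set term, 2691 higher and 2429 lower, and 1770 without replicate 2 of 48 h. When only the groups compared were fitted 623 were called, 480 higher and 143 lower. At 24 h 305 genes differed, 209 higher and 96 lower, against 1687 with the set term, 942 higher and 745 lower, and 97 without replicate 1 of that time. DESeq2 with the set term gave 1009 higher and 976 lower. At 48 h 1286 differed, 776 higher and 510 lower, against 3892 with the set term, 2042 higher and 1850 lower, and 612 and 406 without replicates 1 and 2. The single DMSO library of each time was assumed to vary like the other groups.

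DMSO alone was compared with 0 h to see what the solvent and time in culture did. Among named genes of the RA response, Rarb was at 0.696 CPM after 24 h and 1.81 CPM after 48 h of DMSO against 0.77 ± 0.308 CPM at 0 h, Pou5f1 at 2310 and 2690 CPM against 2120 ± 292 CPM, and Gata6 at 3.76 CPM at both times against 1.92 ± 1.62 CPM. At 24 h edgeR called 0 genes (634 at an unadjusted p under 0.05, where 807.8 are expected by chance), and DESeq2 called 0. At 48 h edgeR called 0 (725 at an unadjusted p under 0.05), also with the set term (1112 unadjusted), while DESeq2 called 2, Gm8199 and Gm12901 (each 0 counts in that library), and with the set term 3, Trim44 (-1.14), Ccng2 (1.63, a gene also higher with RA) and Ap3b2 (1.64), all named after their values were seen. Ap3b2 was higher with RA too, with log2 changes against 0 h of 2.09 at 6 h and 4.67 at 48 h. With 1 library per DMSO time the power was low. On simulated counts with this layout, 1% of genes changed 2-fold and 41% of genes changed 4-fold were recovered, or 34% and 77% with the set term.

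Binding of RAR and RXR was deposited as a single list of 13791 regions for the whole series, with 3 columns for chromosome, start and end on mouse build mm9, and without scores, samples or times. Each region spans 500 bp, and the widths add up to 6.896 Mb on 20 chromosomes, without a check for overlaps between regions. Chromosome 11 held the most regions, 1181 (8.56%, 9.96 per Mb), and chromosome X held 318. The regions were clustered, with 7229 (52.4%) having a neighbour within 10 kb against a mean of 1539 (11.2%) and at most 1663 in 200 uniform placements along the chromosomes. Uniform placement ignores where genes lie, so clustering beyond that of genes was not tested. Regions were not merged, so any that overlap or adjoin at a single site count as neighbours too. The densest windows of 100 kb held 18 regions each, at 88157474 to 88240835 on chromosome 12 and at 29536122 to 29634235 on chromosome 17. Across the 20 chromosomes the number of regions followed the number of tested genes, with Pearson's r = 0.882 and Spearman's rho = 0.877 (each permutation p = 1e-05, the smallest that 100000 permutations can give), and r = 0.808 without chromosomes 2 and 11. A longer chromosome can hold more of both, and length was not adjusted for. Gene positions on mm9 were not available here, so regions were not assigned to genes, and changes in binding between the ChIP times were not analysed here.

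**Figure D5:**
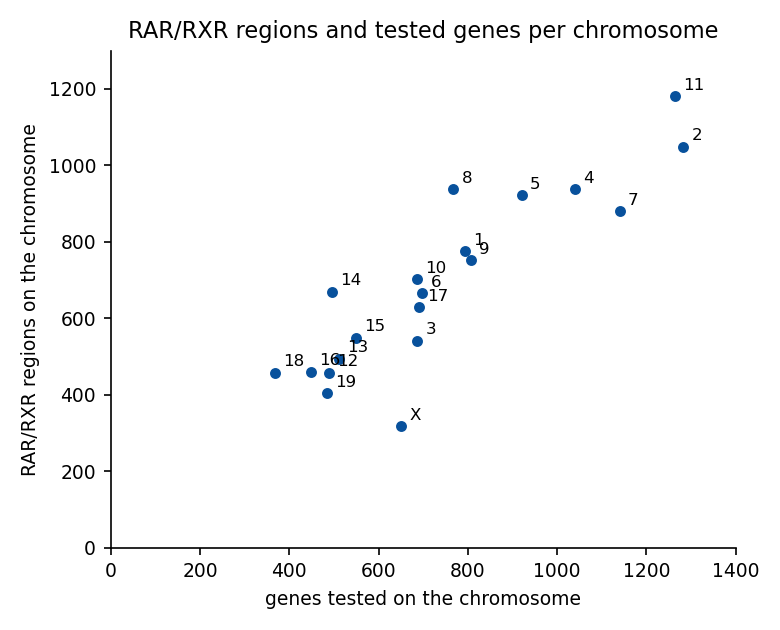
RAR and RXR regions per chromosome against the number of tested genes on it, with 1 point per chromosome. Counts of regions rise with counts of genes (r = 0.882), and chromosome 11 lies highest with 1181 regions.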

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

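Tests of the top-10 share, of pairs of libraries across sets, of library composition and of time in culture were chosen only after the results were seen. In the 4 libraries at 0 h, 119 values were examined for a library far from the others, and 17 were found where chance gives about 1 in 20. The ratio given is the gap of that library to its nearest neighbour over the range of all 4. Replicate 1, the 1 library of set 1, stood apart in the share of reads given to no feature (57.6% against 52.5 to 53.1%, ratio 0.881), in genes detected (17400 against 18800 to 18900, 0.952) and in the CPM of Foxa2 (0.601 against 0.186 to 0.211, 0.941), Lama1 (107 against 38.9 to 50.3, 0.832), Tbx3 (148 against 36.9 to 49.1, 0.89), Pcna (529 against 203 to 236, 0.897), Pim1 (142 against 58.3 to 62.1, 0.955) and Tpm1 (79.2 against 97.4 to 100, 0.862). Replicate 2 stood apart in Nanog (410 against 270 to 291, 0.853), replicate 3 in Dnmt3l (342 against 160 to 190, 0.833) and Clic5 (2.85 against 5.86 to 6.34, 0.864), and replicate 4 in Hoxb1 (0.973 against 0.15 to 0.211, 0.926) and Rxrg (23.5 against 7.37 to 9.28, 0.881). Ttr, Hoxc5 and Dcn each had 1 count in 1 of the 4 libraries, which makes the ratio 1 by construction. Ctsh had 3 counts in all, and its ratio (0.884, 0 CPM in replicate 1 against 0.0932 to 0.105) rests on 1 count per library. Foxa2 and Hoxb1, at under 1 CPM, also rest on few counts.

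The difference between RA and DMSO was itself tested between 24 and 48 h. Without the set term edgeR called 0 genes (680 at an unadjusted p under 0.05), and with it 10 (1585 unadjusted), 7 with a more positive difference at 48 h and 3 with a more negative one, counted by sign. They include laminins Lama1 (2.07 ± 0.28, adjusted p = 0.026) and Lamb1 (2.48 ± 0.36, adjusted p = 0.04), the growth factor Igf2 (4.42 ± 0.64, adjusted p = 0.04), imprinted Peg3 (2.79 ± 0.35, adjusted p = 0.025) and Fst (5.70 ± 0.94, adjusted p = 0.049). For Fst the difference went from -4.76 at 24 h to 0.93 at 48 h with that term, so it shrank in size. Each time has 1 DMSO library, so this test rests on single libraries.

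A split of the libraries by set was the first pattern weighed, with 6794 genes differing between the sets. Library size was argued against, since 6375 genes still differed after thinning every library to 7078941 counts. A different point of the RA response as the main source was argued against by r = 0.0239 across 11351 genes between the set difference at 0 h and the change from 12 to 48 h. Set 1 has a single library at 0 h, but over all 7 pairs of libraries of a group across sets r also stayed between -0.0665 and 0.0517. A smaller shift beneath the set difference is not excluded. On the main axis of variation set 2 lay higher than set 1 at each RA time, such as -13.98 against -29.26 at 6 h and 106.9 against 89.89 at 48 h. Reads shared with numbered pseudogene copies were argued against, since 325 genes with such copies had a median difference of 0.0183, at percentile 74 of 10000 lists matched for expression (-0.0616 to 0.0567 for the central 95%). Counts without a unique position also separated the sets, at 33.12 to 38.31% of all counts in set 1 and 42.32 to 50.95% in set 2. Whether read length lies behind that share could not be tested, since the labels do not say which library had which. Instrument, read length, day of preparation and culture stay open as sources, since no label separates them, and no biological explanation beyond the point of the response was tested.

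Replicate 1 of 24 h RA was the next pattern, apart from replicate 2 with a chi-squared per degree of freedom of 66.92, against 34.51 to 40.96 for the other pairs across sets. An exchange of labels with replicate 1 of 48 h was argued against, since on the axis from 12 to 48 h the latter lay 0.43 (bootstrap SD 0.00825) further along, at 0.853 against 0.424. A few genes taking its counts were argued against by a share of 4.09% in its 10 highest genes, within 3.45 to 4.27% in the other libraries. A culture further along the response cannot be told apart from other sources, because the correlation across genes of its deviation with the change from 12 to 48 h (r = 0.113, rho 0.0722) fell between the bounds of 0.1 and 0.3 set beforehand. Across genes such a correlation does not count independent replicates. On the axis above replicate 2 lay at 0.408, close to replicate 1.

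The fall of ribosome-making transcripts at 48 h, over 99 tested genes of ribosomal proteins and ribosome biogenesis, was the last. Library composition was argued against by the other genes of like level. In 4 pairs of a 48 h and a 0 h library of the same set, scaled to library totals alone, their median change was 0.0169 to 0.166 of that of the 99 genes, which was -0.914 to -0.555. Shared reads with processed copies could not be decided on. The 35 members without a numbered copy had a median of -1 (central 95% of 10000 lists matched for expression -0.545 to -0.12). That is percentile 0.01, the smallest that such lists can give. Copies were counted only where they carry a numbered form of the gene's symbol, so these members can have copies under other names. The 35 were drawn from both lists, and ribosomal protein genes were not tested alone. Time in culture cannot be told apart from RA as the source, because DMSO at 48 h is a single library. In it the median was -0.198 against -0.921 with RA, a ratio of 0.215 with the set term, and 13 of the 99 genes were called lower with RA than with DMSO at 48 h, or 42 with that term. A response to RA, slower growth and a direct effect on these genes stay open too.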

How the results depend on the processing

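Single genes were compared where the rule named them, and fixed genes at 48 h and wherever else they were called. Among these values 4720 kept their direction and side of the threshold, 313 lost a call (233 of them with 1 library left out), 6 gained one and 1 reversed, and among counts 165 stayed within 1.5 times, 64 rose and 32 fell beyond that. The one reversal was Actb at 48 h, which ranged from -0.84 without replicate 1 of 48 h to 0.31 without replicate 2 and was called in neither of these. Calls gained outside this tally include those of Rara at 6 h, Pou5f1 at 24 h and Nanog between RA and DMSO with the library-set term. RLE normalization and the stricter filter kept every count within 1.5 times. For each change below the cause was not tested, except that the groups-only and left-out fits use fewer samples. The library-set term, set 2 alone and their combinations were chosen after seeing the data. DESeq2 called 522 genes at 6 h, 932 at 12 h, 4 for 12 against 6 h, 317 for 24 against 12 h, 654 for 48 against 24 h, 835 and 2174 for RA against DMSO at 24 and 48 h, and 2 for DMSO at 48 h. Without a filter 24 were called for 24 against 12 h. With the replicate block the counts were 798 at 6 h, 1481 at 12 h, 4336 at 24 h, 15, 1801 and 2573 between successive times, and 7495 over the time course. With 1 surrogate variable, which correlated with the library set at 0.9953, they were 942, 2075, 4826 and 7959 at 6, 12, 24 and 48 h, 3, 1020 and 1815 between successive times, 1767, 3927 and 5133 for RA against DMSO at 24 h, 48 h and pooled, and 7844 over the time course. The library-set term gave, in the same order, 906, 2050, 4689 and 7881, then 3, 1012 and 1781, then 1687, 3892 and 5120, and 7753. That term without replicate 1 of 24 h gave 1008, 2387, 3171 and 8242, then 5, 63 and 777, then 587, 4358 and 4266, and 7832. DESeq2 with that term gave 1073, 2320, 4589 and 7279, then 33, 1574 and 1900, then 1985, 3734 and 4921, with 3 for DMSO at 48 h and 7761 over the time course. An absolute log2 fold change of at least 1 left 3128 at 48 h. With only the groups compared, 1181 were called at 24 h, 0 for 24 against 12 h and for 48 against 24 h, and 623 for RA against DMSO pooled. Set 2 alone gave 8 for 24 against 12 h and 179 for 48 against 24 h. With an estimated correlation 4, 6 and 11 lists differed at 6, 24 and 48 h and 8 between RA and DMSO.

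With 1 library left out, counts ranged from 107 to 293 at 6 h, 167 to 480 at 12 h, 712 to 2127 at 24 h and 2731 to 4692 at 48 h. They ranged from 0 to 0 for 12 against 6 h, 1 to 67 for 24 against 12 h, 0 to 29 for 48 against 24 h, 97 to 323, 406 to 612 and 1770 to 2729 for RA against DMSO at 24 h, 48 h and pooled, 1929 to 4081 over the time course, and 0 to 0 for DMSO against 0 h at both times. Lists ranged from 5 to 7 at 6 h, 6 to 9 at 12 h, 13 to 14 at 24 h, 18 to 20 at 48 h and 20 to 22 between RA and DMSO. Regions near changed genes and direct repeats were not run for lack of the mm9 genome. The replicate block and set 2 alone give no value for comparisons with DMSO, whose labels give no replicate number and which lie in set 1, and a DMSO library cannot be left out without emptying its group. Depth limits genes with few counts at 0 h, such as Ttr, Hoxc5 and Cyp26b1, to bounds or wide intervals.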

Other observations

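These values were chosen after the results were seen. Of the 237 genes higher at 6 h, 73 were lower at 48 h than at 6 h and 46 were higher (97 and 59 with the library-set term). Among those that came down, the receptor Notch4 went from a log2 change of 1.96 at 6 h to -2.85 at 48 h (difference -4.82 ± 0.37, adjusted p = 0.00018), the transcription factor Foxn4 from 3.19 to -0.88 (-4.07 ± 0.40, adjusted p = 0.00036), the water and glycerol channel Aqp3 from 4.37 to 1.52 (-2.84 ± 0.28, adjusted p = 0.00036), the kinase Pim1 from 1.80 to -0.78 (-2.57 ± 0.45, adjusted p = 0.0042) and Foxp1 from 0.94 to -1.25 (-2.19 ± 0.21, adjusted p = 0.00036). Those that went on rising include the retinoid-binding protein Crabp2, from 1.65 to 4.35, Foxa1, from 3.97 to 6.71, and the annexin Anxa5, from 1.16 to 4.29. Genes selected for a high value at 6 h tend to come down when they are compared with the same 6 h libraries, so the count of decreases is raised by the selection.

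By gene type, 435 long noncoding RNA genes were tested at 48 h, of which 50 were higher and 26 lower than at 0 h. Of 1037 pseudogenes 21 were higher and 58 lower, and of 13135 protein-coding genes 2624 were higher and 1760 lower. Reads from a parent gene can be counted on its pseudogene, so changes of pseudogenes are uncertain.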
